A study of Homo sapiens with 4 samples.

How the data were processed

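RNA of A549 cells, a human lung adenocarcinoma line grown in serum-containing medium, was sequenced after 24 h with or without 0.6 µM GMI, an immunomodulatory protein of the fungus Ganoderma microsporum. Per the labels' protocols, total RNA was extracted with Trizol, RNA integrity numbers were above 7, and 1 µg of RNA went into each library made with the NEBNext Ultra RNA kit. There were 2 control and 2 GMI libraries. Groups and replicate numbers were taken from the labels. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

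The deposited files hold FPKM values, fragments scaled to gene length and library size, given to 2 decimals for 57905 Ensembl genes in each library. Per the submitters' processing notes, bcl2fastq 2.17.1.14, cutadapt 1.9.1, HISAT2 2.0.1 and HTSeq 0.6.1 were used with the build GRCh37. The gene annotation release, the strand setting of the counting and the gene lengths behind the FPKM are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart. Read counts were not analysed here, so tests made for counts, which had been planned as the main and alternative tests in case counts were given, were not run, and the FPKM test fixed before the data were examined became the main one.

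Gene names came from the files, and 51996 of the 57905 identifiers also had a name in a current gene table. In the files, 29 symbols had been turned into dates by a spreadsheet, and these genes were followed by their identifiers. GENCODE 29, which is on another build, was used only for gene length, GC content, gene type and the share of exons that overlap other genes, and covered 52338 identifiers. No coordinates are printed because the annotation of the files' build was not used here.

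Depth was read from the values themselves. In genes no longer than 200 nt and below 20 FPKM, FPKM values are whole multiples of the value of 1 fragment, within a rounding half-width of 0.006 FPKM. The library denominator that made most values whole was 20560000 fragments for control replicate 1, 24090000 for control replicate 2, 21860000 for GMI replicate 1 and 20880000 for GMI replicate 2. At these denominators 97.4%, 97.3%, 97.9% and 96.9% of the values were whole, against 2.6%, 2.9%, 2.7% and 2.6% expected by chance. An FPKM of 1 in a 2 kb gene then stands for about 41.1, 48.2, 43.7 and 41.8 fragments in these libraries, so genes near the filter rest on few fragments if they are short. The libraries of a group were compared on approximate fragment numbers of genes with at least 50 fragments. The chi-square per degree of freedom was 4.60 for the controls and 8.91 for the GMI libraries, so neither pair was a library deposited in duplicate.

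Genes were tested if their FPKM was at least 1 in at least 2 of the 4 libraries, which left 11598 genes. limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with a mean-variance trend and no covariates, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The prior had 4.69 degrees of freedom and each gene had 2 residual ones. Every log2 fold change is GMI over control on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. FPKM values are given as mean ± SD over the 2 libraries of a group. Data tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

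A file of 40 gene lists with 1183 entries was written before the data were examined, and 2 entries had no match in the files. The 34 lists with at least 5 tested genes were tested with camera from limma with a preset inter-gene correlation of 0.01, and adjusted over the lists. Each list was also tested with an estimated correlation and with fry, whose directional p asks whether the genes of a list move one way without comparing them to other genes. The number of members past the threshold is given over all genes tested and, where stated, adjusted over the list alone.

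The rule for named genes was also fixed before the data were examined. Among genes past the threshold, with both GMI libraries on the same side of both controls and a mean FPKM of at least 5 in 1 of the groups, it takes the 8 with the highest and the 8 with the lowest log2 fold change. It adds up to 3 members with the smallest adjusted p from each list that was called or had at least 2 members past the threshold, and each tested member of a list of candidate genes for GMI whatever its result. This gave 110 genes, and genes named outside the rule are said to be so. Some of the 110 genes, and 1 candidate below the filter, are not reported here.

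On data simulated from the 11598 genes with 200 changed genes in 10 runs, the procedure recovered 99.4% of genes changed 2-fold and 75.5% of genes changed by 0.5 on the log2 scale. Of its calls, 8.9% were genes that had not been changed, above the nominal 5%. It called the changed set in 10 of 10 runs and 0 of 390 unchanged sets. The simulated genes varied independently of each other, and each gene of the changed set was raised 2-fold. These set results therefore do not show how camera does on lists with correlated members or smaller shifts. The shares recovered and falsely called hold for 200 changed genes and noise drawn from the fitted variances. They need not hold for the data, where 1789 genes were called.

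The alternatives set before the data were examined were FPKM rescaled by TMM factors, no filter, a mean FPKM of at least 5, a pseudocount of 0.1, protein-coding genes only, the replicate number as a block, each library left out in turn, an estimated correlation, fry, and the mean in place of the median of a list. After the data had been seen, 2 kinds of alternatives were added. One was limma's voom on approximate fragment numbers, FPKM times GENCODE 29 exon length times the library denominator, for genes and for lists. The other tested each list without the genes that other lists also hold. For the closing section, a list's median was placed among 10000 random lists matched on GC content, length and mean expression.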

Results

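The series measured the transcriptome of A549 cells, a lung adenocarcinoma line, in 2 control libraries and 2 libraries of cells treated with 0.6 µM GMI, a protein of the fungus Ganoderma microsporum, for 24 h. The only comparison the design gives is GMI against control, and its stated purpose was to profile differentially expressed genes. Library denominators, recovered from the FPKM steps, lay between 20560000 and 24090000 fragments. Between 11301 and 11472 genes per library reached 1 FPKM, and the 10 most abundant genes took 17.6% to 18.6% of the summed FPKM. Across genes, log2(FPKM + 1) correlated at 0.995 between the controls, at 0.992 between the GMI libraries and at 0.982 to 0.985 between the groups, where genes are not independent replicates.

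After GMI, 23 of 26 cholesterol synthesis, 23 of 50 lysosome and 12 of 35 autophagy genes had higher RNA levels in A549 cells, and 14 of 35 DNA replication, 17 of 35 ribosome biogenesis and 14 of 24 YAP target genes had lower ones. Camera called these 6 lists, and each lost its call with an estimated correlation of the members (adjusted p = 0.171 to 0.428). That estimate was 0.29 for YAP targets and between -0.023 and 0.014 for the other lists, against a preset of 0.01. With an estimated correlation, camera has only the 2 residual degrees of freedom of the 4 libraries, so these losses do not by themselves show correlated members. The highest fold change of a protein-coding gene among the named genes was that of IGFBP1 (ENSG00000146678), a secreted binding protein of insulin-like growth factors. It rose from 38.8 ± 0.643 to 219 ± 21.4 FPKM (SD, n = 2 in each group as in all values that follow), a log2 fold change of 2.46 (SE 0.077, limma adjusted p = 8.18e-05). The lowest was that of CYR61 (ENSG00000142871, now CCN1), a matricellular protein and a target of YAP. It fell from 73.4 ± 0.615 to 13.5 ± 0.559 FPKM, a log2 fold change of -2.36 (SE 0.061, limma adjusted p = 4.71e-05).

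STC1, a secreted glycoprotein hormone, rose from 6.17 ± 0.615 to 24.2 ± 2.62 FPKM (log2 fold change 1.81), and SMOC1 from 4.0 ± 0.368 to 13.7 ± 0.346 (1.56). RHCG, an ammonium transporter, rose from 12.4 ± 0.544 to 36.3 ± 2.89 FPKM (1.47), and GDF15, a stress-induced cytokine of the TGF-β superfamily, from 85.1 ± 5.42 to 214 ± 11.1 (1.32). At the other end, AMOTL2, an angiomotin family protein, had a log2 fold change of -1.65 and fell from 12.6 ± 1.27 to 3.33 ± 0.290 FPKM. ID2, an inhibitor of basic helix-loop-helix transcription factors, fell from 28.6 ± 0.255 to 9.08 ± 0.714 FPKM (-1.56). The kinase gene PLK2 (-1.44 on the log2 scale) and the Wnt antagonist DKK1 (-1.44) fell alike, as did CYP24A1, the vitamin D 24-hydroxylase (-1.42), ZBED2 (-1.63) and C1orf116 (-1.34). The adjusted p of these genes lay between 0.000304 for ID2 and 0.00121 for C1orf116.

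The rule also took 3 non-coding genes at the upper end, which are uncertain. RN7SL2, a 7SL RNA gene with near-identical copies, had the highest log2 fold change, 2.84 (SE 0.65, adjusted p = 0.0321), but its GMI libraries held 34.7 and 184 FPKM against 11.1 and 9.64 in the controls. Without GMI replicate 2, the log2 fold change of RN7SL2 was 1.65 (adjusted p = 0.00859), and without control replicate 1 or 2 it missed the threshold (adjusted p = 0.199 and 0.234). The unprocessed pseudogene RP11-927P21.4 (1.49) and the microRNA gene MIR635 (1.35, 6.01 ± 2.89 to 16.2 ± 2.18 FPKM) can share fragments with copies or surrounding transcripts.

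In all, 1789 of 11598 genes passed an adjusted p of 0.05 with limma, of which 1079 rose and 710 fell, and 86 of them changed at least 2-fold (53 up, 33 down). At an unadjusted p under 0.05 there were 3733 genes. Leaving out 1 library moved the count: 74 genes passed without control replicate 1, 45 without control replicate 2, 1369 without GMI replicate 1 and 945 without GMI replicate 2, in fits that assume a lone library to vary like the other group. Without a filter on low values 1 gene of 26758 passed, a fall, while 4500 had an unadjusted p under 0.05.

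**Figure D1:**
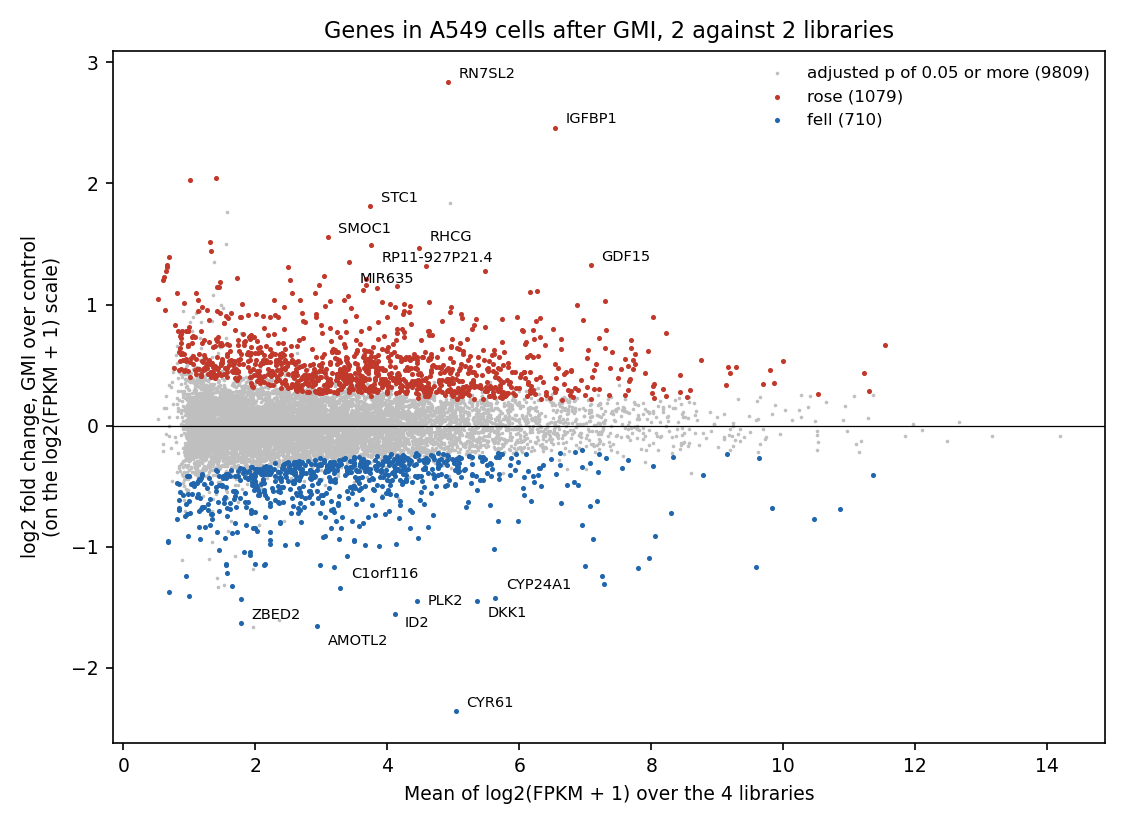
Each point is 1 of the 11598 genes tested, with its mean log2(FPKM + 1) over the 4 libraries on the x axis and its log2 fold change, GMI over control, on the y axis. Genes past an adjusted p of 0.05 are red (1079 that rose) or blue (710 that fell), and the 16 genes at the ends named by the rule are labelled, with RN7SL2 and IGFBP1 at the top and CYR61 at the bottom.

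Cholesterol synthesis genes rose together. Of 26 measured genes of the pathway and its SREBP2-driven regulators, 23 rose, 0 fell and 3 did not pass, with 24 rising when adjusted over the list alone and a median log2 fold change of 0.65. MVD, mevalonate diphosphate decarboxylase, rose from 8.67 ± 0.290 to 20.3 ± 0.134 FPKM (log2 fold change 1.138, SE 0.065, adjusted p = 0.000465). INSIG1, which holds the SREBP complex in the endoplasmic reticulum, rose from 28.9 ± 0.933 to 54.0 ± 3.22 FPKM (0.88, adjusted p = 0.00108). The list shifted by camera (adjusted p = 1.4e-16), with adjusted p = 0.171 with an estimated correlation. Without control replicate 1 or control replicate 2, 2 and 2 of its genes passed the threshold.

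Of 18 fatty acid synthesis genes 6 rose and 2 fell, with a median log2 fold change of 0.10 (camera adjusted p = 0.115, and 0.818 with an estimated correlation). Camera called this list upward with voom (adjusted p = 0.0350) and without genes shared with other lists (0.0390), while 1 and 1 of its genes rose without control replicate 1 or 2. The desaturases SCD (91.5 ± 7.07 to 168 ± 5.03 FPKM, log2 fold change 0.87) and FADS2 (0.57) and the acetyl-CoA synthetase ACSS2 (0.77) rose.

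Part of the lysosome genes rose as well. Of 50 measured, 23 rose, 0 fell and 27 did not pass, and 30 rose when adjusted over the list alone, with a median log2 fold change of 0.23. CTSL, the protease cathepsin L, rose from 109 ± 1.29 to 225 ± 27.0 FPKM (log2 fold change 1.03, adjusted p = 0.00131). ATP6V0B, a subunit of the proton pump that acidifies lysosomes, rose from 21.3 ± 1.33 to 41.7 ± 2.27 FPKM (0.94), and NPC1, which exports cholesterol from lysosomes, from 10.7 ± 0.438 to 20.7 ± 0.990 (0.90). The list shifted by camera (adjusted p = 2.67e-12), with adjusted p = 0.171 with an estimated correlation. The number of its genes that rose was 1 without control replicate 1, 0 without control replicate 2 and 14 without GMI replicate 2.

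Of 35 autophagy genes, 12 rose, 0 fell and 23 did not pass (13 rose adjusted over the list alone), with a median log2 fold change of 0.10. GABARAPL1, of the family that coats autophagosomes, rose from 12.8 ± 0.276 to 21.5 ± 0.495 FPKM (log2 fold change 0.71). WIPI1 rose from 8.53 ± 0.276 to 14.2 ± 0.212 FPKM (0.68), and the cargo receptor SQSTM1 from 298 ± 3.51 to 399 ± 1.94 (0.42, adjusted p = 0.00491). The shift by camera had an adjusted p of 0.00206, with adjusted p = 0.353 with an estimated correlation. None of the list's genes passed without control replicate 1 (0) or control replicate 2 (0), and 6 did without GMI replicate 2.

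Part of the genes of DNA replication and division were lower. Of 35 G1/S and DNA replication genes above the filter, 14 fell, 0 rose and 21 did not pass, with a median log2 fold change of -0.30 (1 rose and 23 fell adjusted over the list alone). MCM6, part of the replicative helicase, had a log2 fold change of -0.52 and fell from 5.87 ± 0.106 to 3.78 ± 0.014 FPKM. The cyclin gene CCND1 fell from 88.6 ± 1.12 to 66.4 ± 0.318 FPKM (-0.41), and TYMS, thymidylate synthase, from 9.11 ± 0.354 to 6.99 ± 0.304 (-0.34). Only 14 of 40 G2/M and mitosis genes were above the filter, of which 5 fell and 0 rose (median -0.21). None of those 5 reached 5 FPKM, and CDC20, named after its values were seen, fell from 2.89 ± 0.233 to 0.91 ± 0.049 FPKM (-1.03). Camera gave adjusted p = 3.14e-10 for the replication list and 0.000346 for the mitosis list, with adjusted p = 0.171 and 0.428 with an estimated correlation. Without control replicate 1 or 2, 0 and 0 replication genes passed, and 7 did without GMI replicate 2; of the mitosis list 0, 0, 1 and 1 passed without control replicate 1, control replicate 2, GMI replicate 1 and GMI replicate 2.

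Ribosome biogenesis genes and other MYC targets fell in 17 of 35 cases, with 0 up and a median log2 fold change of -0.31 (27 fell adjusted over the list alone). NOLC1, a nucleolar phosphoprotein, fell from 57.9 ± 2.70 to 36.4 ± 0.092 FPKM (-0.66), NOP16 from 27.0 ± 1.03 to 18.8 ± 0.580 (-0.50) and PA2G4 from 50.2 ± 0.742 to 36.7 ± 0.622 (-0.44). Of 21 DNA repair genes above the filter 6 fell and 0 rose (median -0.18, 9 fell adjusted over the list alone), among them the mismatch repair gene MSH6 (-0.42) and PARP1 (-0.29). Camera gave adjusted p = 3.14e-10 and 0.000441 for these lists, with adjusted p = 0.171 and 0.355 with an estimated correlation. None passed in either list without control replicate 1 or 2 (0 and 0), while 1 repair gene fell without GMI replicate 1 and 2 without GMI replicate 2. Genes of the ribosomal proteins themselves had an estimated correlation of 0.515, against the preset of 0.01. Their median was 0.02, with 4 of 76 up and 2 down over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.784). That result depended on the controls: without control replicate 1 camera called the list upward (adjusted p = 0.0407, median 0.05), and without control replicate 2 the median was -0.02 (adjusted p = 0.132).

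Of 24 YAP target genes measured, 14 fell, 1 rose and 9 did not pass, with 17 falling adjusted over the list alone and a median log2 fold change of -0.37. Besides CYR61 and AMOTL2 they included AJUBA, a LIM domain protein, which fell from 19.7 ± 0.049 to 9.37 ± 0.049 FPKM (-0.996, adjusted p = 0.000565). The gene that rose was IGFBP3 (136 ± 1.15 to 207 ± 2.998 FPKM, log2 fold change 0.61), named after its value was seen. Of 29 genes of TGF-β signalling and epithelial-mesenchymal transition, 12 fell, 2 rose and 15 did not pass (median -0.22, 3 up and 16 down adjusted over the list alone). PMEPA1, a TGF-β target, fell from 81.8 ± 1.63 to 47.1 ± 0.332 FPKM (-0.78). The 2 that rose, named after their values were seen, were VIM, the mesenchymal filament vimentin (529 ± 1.20 to 741 ± 14.6 FPKM, 0.49), and the ligand gene TGFB1 (0.44). Camera gave adjusted p = 2.87e-08 for YAP targets and 1.03e-06 for the TGF-β list, with adjusted p = 0.428 for both with an estimated correlation. The numbers that fell were 4 and 3 without control replicate 1 and 3 and 1 without control replicate 2.

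Of 10 stemness genes above the filter 4 fell and 0 rose (6 fell adjusted over the list alone, median -0.26, camera adjusted p = 0.000865, and adjusted p = 0.353 with an estimated correlation). Named outside the rule, the list members SOX2, NANOG, POU5F1 and LIN28B lay below the filter, so the shift does not cover them. The aldehyde dehydrogenase gene ALDH1A1 had a log2 fold change of -0.77 and fell from 1845 ± 4.24 to 1079 ± 16.8 FPKM. ALDH3A1 fell from 191 ± 4.25 to 99.6 ± 10.2 FPKM (-0.94) and MYC from 42.3 ± 0.290 to 33.8 ± 0.240 (-0.31). Without control replicate 1 or 2, 1 and 1 of these genes passed. Of 10 Wnt genes above the filter, DKK1, BMP4 (-0.64) and PORCN (-0.62) fell and 0 rose, and camera did not call the list (adjusted p = 0.115, and 0.479 with an estimated correlation). It called the list downward with voom (0.0475), with no filter (0.0474) and without genes shared with other lists (0.0362), and 1 and 1 of its genes fell without control replicate 1 or 2.

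Antigen presentation and interferon response genes rose in part. Of 18 antigen presentation genes 9 rose and 0 fell (9 adjusted over the list alone; median 0.29), with HLA-E at 47.3 ± 1.22 and 66.5 ± 1.32 FPKM (log2 fold change 0.48) and B2M at 233 ± 5.88 and 293 ± 21.9 (0.33). Of 30 interferon response genes 10 rose and 0 fell (14 up and 1 down adjusted over the list alone; median 0.24). IFIT3 rose from 9.58 ± 0.679 to 20.6 ± 3.14 FPKM (1.02), and the transcription factor genes STAT2 (8.29 ± 0.495 to 14.97 ± 0.092, 0.78) and IRF7 (0.54) rose with it. Camera gave adjusted p = 0.000346 and 0.00326 for these lists, with adjusted p = 0.479 and 0.818 with an estimated correlation. That estimate was 0.262 for antigen presentation and 0.606 for interferon response, far above the preset of 0.01 on which the calls rest. The interferon list missed the threshold without control replicate 1 (adjusted p = 0.0545). Without control replicate 1 or 2, 0 and 0 members of either list passed, and without GMI replicate 2, 2 and 4 did. Camera did not call NF-κB and inflammation genes, with 6 up and 2 down of 31 and adjusted p = 0.784, where the median was -0.03 and the mean 0.05. These counts were not stable: 3 rose and 5 fell without GMI replicate 1, 2 rose and 1 fell without GMI replicate 2, and 1 rose and 0 fell without control replicate 1 and likewise without control replicate 2. Within it PTGS2, cyclooxygenase 2, rose from 14.1 ± 1.01 to 36.7 ± 1.56 FPKM (1.32) and CCL20 rose (0.69), while CXCL5 fell (-0.63).

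**Figure D2:**
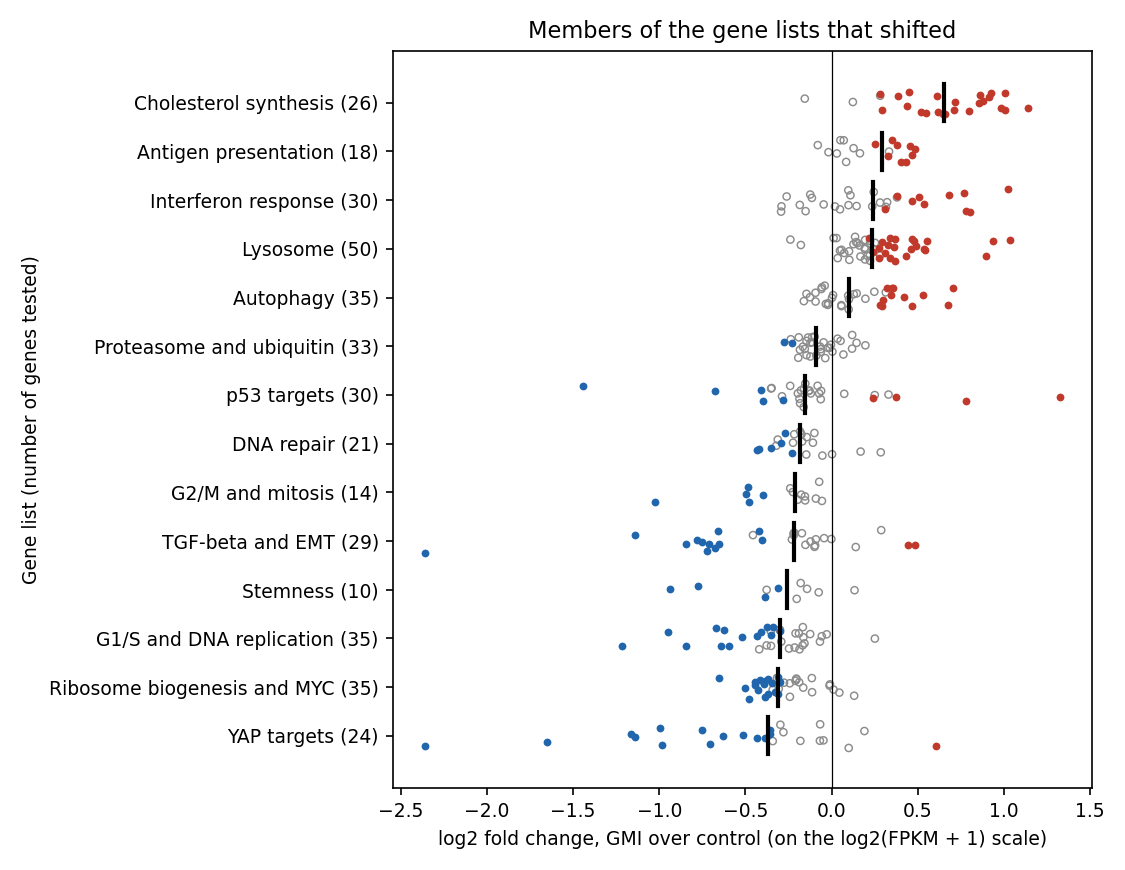
Each row is 1 of the 14 gene lists that camera called, with the number of genes tested in brackets, and each point is a gene at its log2 fold change, GMI over control, on the x axis; vertical jitter has no meaning. Filled red and blue points rose and fell past an adjusted p of 0.05, open points did not pass, and the black bar is the list's median, from 0.65 for cholesterol synthesis to -0.37 for YAP targets.

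The p53, ATF4 and endoplasmic reticulum stress lists each had genes that rose and genes that fell. Of 30 p53 targets 4 rose and 5 fell (5 and 7 adjusted over the list alone), with a median of -0.16. Without control replicate 1 it was 1 up and 2 down, and without control replicate 2 1 up and 1 down. Besides GDF15, the pro-apoptotic BBC3 rose (13.6 ± 0.219 to 24.0 ± 0.184 FPKM, log2 fold change 0.78), while PLK2 fell. Camera called this list downward (adjusted p = 0.0278), with adjusted p = 0.428 with an estimated correlation, and it missed the threshold without control replicate 1 (0.0545) or GMI replicate 2 (0.0509), at a mean FPKM of at least 5 (0.0736) and with protein-coding genes only (0.0501). Of 30 genes of the BCL2, IAP and caspase families 6 rose and 0 fell (camera adjusted p = 0.309), including PMAIP1 (0.50), and 0 and 0 passed without control replicate 1 or 2. Of 29 ATF4 and amino acid response genes 7 rose and 5 fell (camera adjusted p = 0.638, median -0.03, mean 0.08). ATF3 rose from 2.80 ± 0.226 to 7.74 ± 0.516 FPKM (1.20), and TRIB3 (0.73) and DDIT4 (0.71) rose. Of 29 endoplasmic reticulum stress genes 6 rose and 4 fell (camera adjusted p = 0.383). The phosphatase subunit PPP1R15A (0.88) and HERPUD1 (0.49) rose, while the chaperone gene HSPA5 fell from 292 ± 0.735 to 231 ± 7.76 FPKM (-0.34).

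Of 34 hypoxia and glycolysis genes 9 rose and 1 fell (camera adjusted p = 0.103, but 0.0498 without control replicate 1 and 0.0362 with voom), with NDRG1 (0.94), ANGPTL4 (0.95) and CA12 (0.79) among those that rose. Of 23 feedback and target genes of MAPK signalling 8 rose and 5 fell (camera adjusted p = 0.142), but 1 and 0 rose and none fell (0 and 0) without control replicate 1 or 2. Camera called this list upward with no filter (0.0332) and without genes shared with other lists (0.00345, with 7 up and 2 down of 16), and gave adjusted p = 0.729 with an estimated correlation. The ERK phosphatase genes DUSP6 (1.04) and DUSP5 (0.99) rose, and CCND1 fell. NRF2 targets were split, with 3 up and 4 down of 32 (camera adjusted p = 0.65), HMOX1 (0.40) and AKR1C1 (0.56) having risen and GPX2 (-0.73) having fallen. Heat shock genes had 4 up and 4 down of 24 (camera adjusted p = 0.602), with HSPB1 up (0.43) and FKBP4 down (-0.41). Of 33 proteasome and ubiquitin genes 2 fell, PSMD11 (-0.28) and PSMD1 (-0.23), and 0 passed adjusted over the list alone or without control replicate 1, control replicate 2 or GMI replicate 1 (0, 0 and 0). Camera gave that list adjusted p = 0.0426, with adjusted p = 0.818 with an estimated correlation, and it missed the threshold after TMM rescaling (0.0524), with a replicate block (0.0691), at a mean FPKM of at least 5 (0.0614), with protein-coding genes only (0.0544), without control replicate 1 (0.257) and without GMI replicate 1 (0.267).

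A list of 19 candidate genes drawn up from what is known of GMI had 14 members above the filter, of which 1 rose and 4 fell, and camera did not call it (adjusted p = 0.49). The candidates' calls were lost when either control was left out. In those fits the residual spread of a gene comes from the GMI pair alone. The losses therefore do not show that a candidate's change depends on having both controls. The list's median was -0.063 in the main test, -0.058 without control replicate 1 and -0.075 without control replicate 2. The receptor gene EGFR fell from 18.6 ± 1.32 to 13.4 ± 1.44 FPKM (log2 fold change -0.45, SE 0.091, adjusted p = 0.0218). SNAI2, a repressor of epithelial genes, fell from 10.7 ± 0.863 to 6.12 ± 0.106 FPKM (-0.71, adjusted p = 0.00316), MYC fell (-0.31), and SQSTM1 rose. Of the candidates, 9 did not pass, among them MAP1LC3B (0.25, adjusted p = 0.104), CTNNB1 (0.17, 0.0874), ATP6V0A1 (0.17, 0.162), AKT1 (-0.04, 0.701), ERBB2 (-0.04, 0.696), CDKN1A (-0.08, 0.359), PTK2 (-0.18, 0.178) and MTOR (-0.19, 0.256). Named outside the rule, the candidate BIRC5 lay below the filter, at 0.64 and 0.58 FPKM in the controls and 0.47 and 0.38 with GMI, and TMPRSS2 and PROM1, also outside the rule, were at or below 0.03 FPKM in each library. CD274, likewise below the filter and outside the rule, stood between 0.52 and 0.61 FPKM. Of 17 genes in the list of ERBB receptors and adaptors 5 fell and 0 rose (camera adjusted p = 0.0851, and 0.479 with an estimated correlation). Among them were SHC1 (-0.47) and AXL (45.5 ± 2.18 to 29 ± 0.368 FPKM, -0.63), a receptor that is not itself of the ERBB family. Camera called this list with voom (0.0475), but without genes shared with other lists 2 of 11 fell and the adjusted p was 0.707.

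Extracellular matrix and protease genes had 6 up and 5 down of 29 (camera adjusted p = 0.784). The urokinase gene PLAU rose from 191 ± 0.438 to 357 ± 13.3 FPKM (0.90), its receptor PLAUR from 51.4 ± 1.37 to 112 ± 8.57 (1.11) and the integrin gene ITGA2 from 4.21 ± 0.438 to 10.6 ± 0.856 (1.16). Epithelial junction and keratin genes had 4 up and 3 down of 18 (camera adjusted p = 0.784), with ELF3 (0.92) and JUP (0.52) up and KRT7, keratin 7, down from 1147 ± 41.3 to 510.0 ± 11.9 FPKM (-1.17). Glycosylation genes had 1 up and 2 down of 31, nuclear oxidative phosphorylation genes 3 up and 1 down of 48, mitochondrially encoded genes 1 up and 0 down of 13, histone genes 1 up and 1 down of 11, and coagulation and acute phase genes 3 up and 1 down of 7, and camera called none of these 5 lists (adjusted p = 0.581, 0.601, 0.887, 0.601 and 0.581).

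The genes named in this paragraph lie outside the rule and were chosen after their values were seen. None of the fibroblast or lymphoid markers passed the filter, and PTPRC, CD3D and CD3E were listed at 0 in the 4 libraries. Of the 2 myeloid markers above the filter CD14 rose from 2.06 ± 0.078 to 4.11 ± 0.707 FPKM, and of the 2 neuroendocrine markers ENO2, also a glycolysis gene, rose from 18.0 ± 0.566 to 27.1 ± 0.240. Of the endothelial and alveolar type 2 markers 1 and 2 were above the filter and 0 passed the test.

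**Figure D3:**
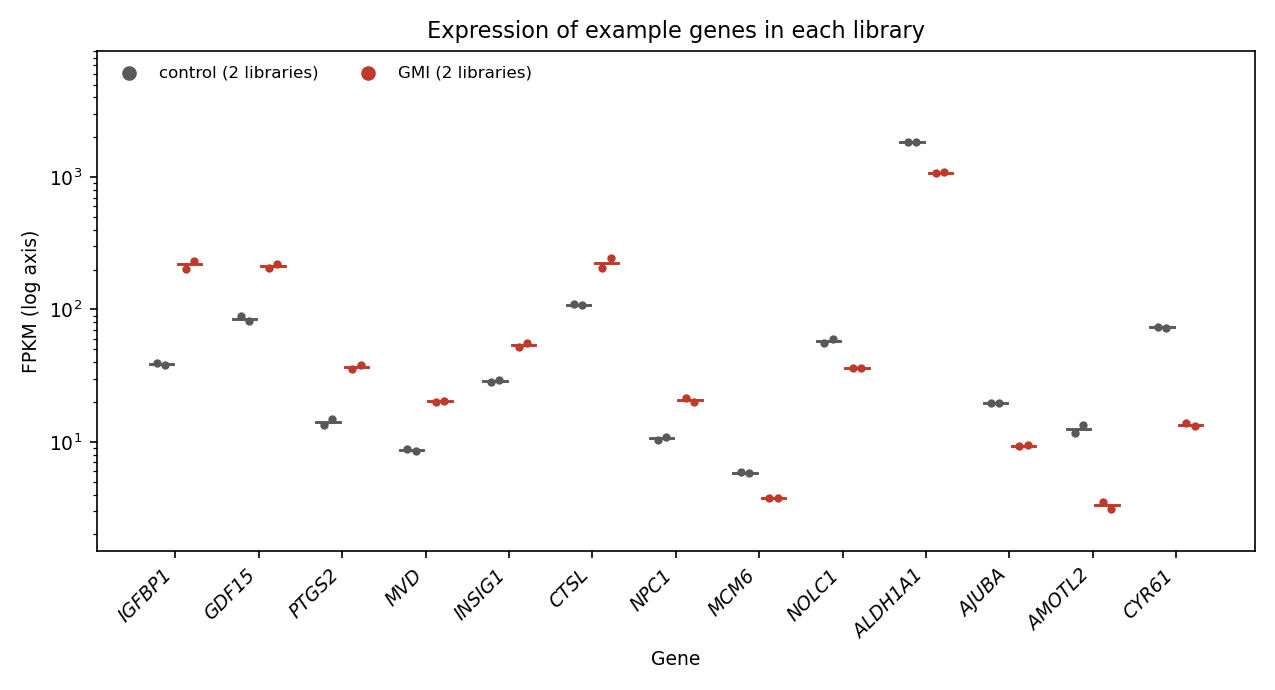
FPKM on a log axis of 13 example genes, with 1 point per library (grey for the 2 controls, red for the 2 GMI libraries) and a bar at each group's mean. IGFBP1 lies near 38.8 FPKM in the controls and 219 with GMI, and CYR61 near 73.4 and 13.5, with the libraries of a group close to each other.

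Camera called 14 of 34 lists at an adjusted p of 0.05 and 0 with an estimated correlation of the members, where 4 had an unadjusted p under 0.05. Fry also called 14 lists, but not the same: it called ATF4 (adjusted p = 0.0242), Wnt (0.0187) and hypoxia (0.0334), which camera did not, and left out antigen presentation, interferon response and the proteasome. In the 20 lists that camera did not call, at most 3 genes of a list rose and at most 1 fell without control replicate 1 or 2. Of the 110 named genes, 9 of which had not passed the test, 72 lost their call without control replicate 1, 77 without control replicate 2, 10 without GMI replicate 1 and 16 without GMI replicate 2, and none changed direction in these fits. Because the strand setting of the counting is not stated, values are uncertain for genes whose exons overlap other genes in GENCODE 29: DDIT4 by 41.2% of its exon length, DUSP6 by 40.5%, TYMS by 39.1%, PLAU by 31.1%, WIPI1 by 24.3% and SQSTM1 by 20.7%.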

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

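The count of 1789 genes stayed within 1.5 times under TMM rescaling (1838), a mean FPKM of at least 5 (1708), a pseudocount of 0.1 (1744), protein-coding genes only (2536) and voom on approximate fragments (2549), chosen after seeing the data. The share of calls that rose was 60.3%, and 53.9% to 62.5% in these fits and those without 1 library. With no filter on low values 1 gene passed, 0 up and 1 down, and 1 changed at least 2-fold; limma's prior degrees of freedom were 1.73 there and 4.69 in the main test. Without 1 library, 45 to 1369 genes passed, with 28 to 856 up, 17 to 513 down and 39 to 128 at least 2-fold; each fit has 1 residual degree of freedom. Of the 74 and 45 genes called without control replicate 1 and 2, 72 and 44 were among the 1789. Falls numbered 1150 in protein-coding genes and 1174 with voom, against 710. Genes changed at least 2-fold numbered 50 at a mean FPKM of at least 5, where fewer genes are tested, and 207 with a pseudocount of 0.1 and 199 with voom, which shrink low values less, against 86. With no filter, 100 of the 110 named genes lost their call, and no named gene reversed in any alternative. Planned count tests were not run, since only FPKM was analysed.

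With the replicate block, 2000 genes passed (1191 up, 809 down, 100 at least 2-fold) and 13 lists; the proteasome list lost its call (adjusted p = 0.0691), as did PSMD1 and HIST1H2BK. Deviations of same-numbered libraries correlated at -0.04 across genes, so the numbers were not taken to pair the libraries.

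Among the called lists the estimated correlation was 0.61 for interferon response and 0.29 for YAP targets and the proteasome. It was 0.26 for antigen presentation, 0.19 for mitosis, 0.17 for the TGF-β list and between -0.046 and 0.023 for the rest, against a preset of 0.01. Against 14 lists called, an estimated correlation left 0, where the test has only the 2 residual degrees of freedom of the 4 libraries. Others gave 13 (TMM), 11 (mean FPKM of at least 5, with the mitosis list too small to test), 12 (protein-coding genes only), 14 (pseudocount of 0.1), 16 (no filter), 13 to 14 (1 library left out), 14 (fry), 18 (voom) and 17 (without shared genes, added after seeing the data). Fry did not call antigen presentation, interferon response or the proteasome (adjusted p = 0.0597, 0.211 and 0.266), and called ATF4, Wnt and hypoxia instead. No called list reversed. Without shared genes, YAP targets had a camera adjusted p of 4.47e-05 (20 genes) and the TGF-β list 0.00949 (21 genes). Their medians were then -0.35 and -0.15, against -0.37 and -0.22 with the shared genes, so part of the TGF-β shift came from genes that other lists also hold.

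Medians of several uncalled lists changed sign in some fit; the cause was not tested. The ATF4 median stayed negative, but its mean was 0.079, as NF-κB's was 0.053 and that of the mitochondrially encoded genes 0.0038. Medians were -0.095 for coagulation, -0.061 for epithelial junctions and -0.0046 for hypoxia at a mean FPKM of at least 5, and 0.029 for extracellular matrix and 0.020 for ERBB without shared genes. Without 1 library, medians ran from -0.023 to 0.011 for NRF2, -0.034 to 0.0062 for NF-κB, -0.0059 to 0.067 for epithelial junctions, -0.0089 to 0.065 for hypoxia, -0.0041 to 0.077 for nuclear oxidative phosphorylation, -0.070 to 0.098 for mitochondrially encoded genes, -0.024 to 0.050 for ribosomal proteins and -0.14 to 0.012 for histones.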

Other observations

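Other genes changed as well, all chosen after their values were seen. The helix-loop-helix inhibitor genes ID1 and ID3 fell with ID2. ID1 fell from 363 ± 17.5 to 170 ± 6.72 FPKM (SD, n = 2; log2 fold change -1.09, limma adjusted p = 0.000465) and ID3 from 191 ± 9.85 to 85.0 ± 6.20 (-1.16, adjusted p = 0.000565). The inhibitory SMAD genes SMAD6 (7.15 ± 0.212 to 4.04 ± 0.417 FPKM, -0.70) and SMAD7 (10.96 ± 0.212 to 6.58 ± 0.035, -0.66) fell too. CAV1, caveolin 1, fell from 333 ± 10.4 to 147 ± 10.6 FPKM (-1.18). In the TGF-β list the connective tissue growth factor gene CTGF fell from 3.35 ± 0.156 to 0.98 ± 0.191 FPKM (-1.14).

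Of 40 G2/M and mitosis genes, 26 lay below the main filter, and the 5 named here were chosen after their values were seen. MKI67, a marker of dividing cells, stood at 0.19 and 0.23 FPKM in the controls and 0.04 and 0.02 with GMI, CDK1 at 0.72 and 0.67 against 0.16 and 0.13, and FOXM1 at 1.09 and 0.91 against 0.51 and 0.58. Among the 26, only AURKB (0.48 and 0.45 against 0.55 and 0.62) did not have a lower mean with GMI. CENPF (0.32 and 0.28 against 0.26 and 0.27) was only slightly lower. Without a filter on low values 0 of the 40 genes passed the test, while camera called the list downward (adjusted p = 8.28e-11). With an estimated correlation, run only on the 14 genes above the main filter, camera did not call it (adjusted p = 0.428).

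The patterns below were seen first in TUBA4A and TUBB4B, in the cholesterol list, and in RN7SL2, MIR635 and other short RNA genes. For tubulin and short RNA the tests were set before the class values were computed, except the test of a paralog in each family and the tubulin values without TUBA4A and TUBB4B, which were chosen after. The median of the cholesterol list was already known, and only its place among random lists and the LXR values were not.

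Of 10 alpha- and beta-tubulin genes above the filter 8 fell and 1 rose, with a median log2 fold change of -0.84: TUBA4A fell from 244 ± 4.19 to 98.1 ± 1.45 FPKM (-1.31), TUBB4B from 233 ± 5.84 to 98.3 ± 3.32 (-1.24) and TUBB from 363 ± 7.20 to 193 ± 14.6 (-0.91), while TUBA1A rose (0.31) and TUBB4A did not pass (-0.25, adjusted p = 0.11). GC content, length or expression level is argued against, since the 8 genes other than TUBA4A and TUBB4B, which prompted the test, had a median of -0.74 at percentile 0 of 10000 matched random lists (2.5% below -0.125 and 2.5% above 0.237), and the median of the 10 together lay at percentile 0 as well. Reads shared with 1 fallen paralog are argued against, since both families fell, with medians of -0.74 (alpha) and -0.88 (beta), and -0.66 and -0.85 without TUBA4A and TUBB4B. Reads shared with 1 fallen paralog in each family stay open. The other beta genes lost 1.44 FPKM, and the other alpha genes 0.740, per FPKM lost by TUBB4B and TUBA4A. Only a ratio above the number of other genes, 5 beta or 3 alpha, would have argued against such sharing, so these ratios cannot decide. The source was taken to be the gene with the deepest log2 fall. TUBB lost more FPKM than TUBB4B, and TUBB as the source was not tried. Another candidate explanation is a larger pool of free tubulin dimers, which is known to speed the decay of alpha- and beta-tubulin mRNA. The alpha and beta median lay 0.81 below that of 10 other tubulins and folding cofactors (difference -0.81, and -0.72 without TUBA4A and TUBB4B). The median of those 10 was -0.02, so the difference largely restates the fall. It does not tell a larger dimer pool from other causes that act on alpha and beta genes. Against a larger pool as the whole cause, TUBG1, a gamma-tubulin gene, fell as well (-0.84, adjusted p = 0.000951) and TUBA1A rose, so lower transcription stays open too and was not tested.

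For the rise of cholesterol synthesis genes, GC content, length or expression level is argued against, since the list's median of 0.65 lay at percentile 100 of matched random lists, of which 2.5% lay below -0.08 and 2.5% above 0.10. A hypothesis is that the treated cells sensed low sterol, in which case targets of LXR, the receptor of oxysterols, may fall. The median of the 6 of 11 LXR targets above the filter was -0.12, at percentile 11.3, inside the range of random lists. LPCAT3 fell (-0.33) and SMPDL3A rose (0.58), so the 6 genes do not decide. NPC1 rose in the same libraries.

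Short non-coding RNA genes stood at the upper end, led by RN7SL2. However, the class of 128 genes up to 400 nt, which does not hold RN7SL2, had a median log2 fold change of 0.02. In it 11 genes rose and 7 fell, against 1079 and 710 of all 11598 genes tested. The shares called do not set the class apart from all genes. Carry-over of short RNA into the GMI libraries could raise such genes, and the class median lay at percentile 87.9 of random lists matched on expression, neither high nor low enough to decide. Carry-over that differs between libraries of 1 group is also open: the larger within-group median difference, 0.11 between the controls, was 6.35 times the class median. By the reading set beforehand that ratio would count for it, but with a class median this close to 0 the ratio was judged void after it was seen. The difference of RN7SL2 between 34.7 and 184 FPKM in the GMI libraries remains without a tested explanation.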
